A study of Mus musculus with 57 samples.

How the data were processed

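Messenger RNA was measured in 57 single sensory neurons from mouse dorsal root ganglia. Per the labels' protocols, the ganglia came from mice that carry the calcium indicator GCaMP6s in sensory neurons that express Cre from the advillin locus. The neurons were dissociated and cultured for 24 h, then stimulated with focused ultrasound at 20 MHz, in pulses of 0.1 to 1 ms whose pressure peaked at 4 to 5 MPa. After the calcium recording the cytoplasm of each neuron was drawn into a glass pipette, amplified with the SMART-Seq v4 kit, and 0.5 ng of the product went into a Nextera XT library. GEO's labels give the sex of the mouse, and a deposited sample table gives its age in weeks, a library pool code and whether the neuron responded to ultrasound.

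A pair of expression tables was deposited. The first holds log2 values that the authors made, as deposited, from read counts scaled per neuron, as log2(scaled count + 1). That scale was read from the values, and the table's name refers to TMM, a method for computing library scaling factors. In each neuron the linear values were whole multiples of a single step, so whole reads could be recovered: 100% of nonzero values came within 0.1 read of a whole number. The recovered reads were used for depth only. The second table holds TPM as deposited by the authors, a length-scaled share of transcripts that keeps no depth. The submitters' processing notes name bcl2fastq 2.20.0.422, FastQC and Subread, with the builds mm10 and GRCm38, and give them no role or order. The aligner settings, the annotation, the strand setting and the treatment of reads shared between genes are not given in the sources used here. The deposited sample table has no response amplitude, so expression was not related to amplitude.

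The table of log2 values lists 26546 genes by Ensembl identifier, of which 26520 matched a symbol of the GENCODE vM21 annotation of GRCm38. Tafa4 appears there under its older symbol Fam19a4. Genes with a scaled count of at least 1 in at least 10% of neurons were kept, which left 21793 genes. List members are called measured where they passed this filter. Values are given as log2(scaled count + 1), with a pseudocount of 1. A difference of 1 on this scale is a doubling of the scaled count + 1, and it understates the change of genes near 0. Recovered reads ranged from 1071315 to 6301826 per neuron (median 3194543), and 7628 to 18431 genes were detected. No pair of neurons was a duplicate, with a highest correlation of 0.886. Mitochondrially encoded genes were at 0 in the TPM table for all neurons and absent from the other, so that list could not be measured.

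Each sample is 1 neuron, and no animal, culture or recording day is named. The design fixed before the data were examined calls for no test in that case, because neurons of a culture are not replicates. The main results are therefore differences between class means, with the SD over neurons as a description of their spread. Each gene list fixed beforehand was described by the percentile of its median difference among 10000 random lists of the same size matched on mean expression. Some genes, such as Gfra2, Trpc3, Scn1a and Ntrk2, belong to more than 1 list, so the lists are not separate evidence. Shares of neurons with a marker count neurons at a scaled count of 10 or more, with exact Clopper-Pearson 95% intervals that cover counting error only. The 6 sets of neurons that share a labelled sex and age, of which 4 hold both classes, and the library pools were used to see whether a difference kept its direction.

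The rule for named genes took the 12 highest and 12 lowest differences among genes with a scaled count of at least 1 in at least 50% of the neurons of the higher class and a mean of at least 3 there. Predicted genes, ribosomal protein genes and immune receptor segments were not named. Phf24, 2 to 4 members of each list by size of difference, and the Y-linked and Xist genes were added, along with further list members where a group is described.

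As an alternative chosen after seeing the data, limma 3.58.1 in R 4.3.3 (empirical Bayes with trend, Benjamini-Hochberg adjustment, threshold 0.05) was run on set means, paired over the 4 sets, with camera for the lists, and on 6 set means for sex. These sets are not labelled as animals, and they are separate animals only if the sex and age labels hold. The code was tested on simulated data made by shuffling each of 21793 genes separately over neurons and shifting 200 of them. The shifted genes were drawn only from genes with higher mean values, so the recovery below does not cover genes of low expression. For responding against non-responding neurons, limma recovered 2.99% of shifts of 2, 64.2% of shifts of 4 and 89.4% of shifts of 6 on the log2 scale, with 0 false calls. For male against female neurons it recovered 2.99%, 61.2% and 83.3%, with 0 false calls. With nothing shifted, 1 of 21 lists had a median outside the central 95% of random lists, and a list shifted by 2 lay at percentile 100. Separate shuffling removes the correlation between genes and any structure of the sets. The simulation therefore cannot show how often real lists whose genes move together are called by chance. Other alternatives were pseudocounts of 0.1 and 10, the TPM table, other low-value filters and each labelled sex alone. Medians, other presence thresholds, and neurons or sets left out were also used. Figures were drawn with matplotlib 3.10.9.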

Results

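Transcriptomes were obtained from 57 single dorsal root ganglion neurons, the sensory neurons that carry touch, pain, itch and temperature signals from the body. After ultrasound stimulation under calcium imaging, 45 neurons were classed as responding and 12 as non-responding. By label, 36 came from males and 21 from females, at 10 to 15 weeks of age. Depth was similar in both classes, with 3296000 ± 1131300 recovered reads per responding neuron (SD, n = 45 neurons) and 3235800 ± 1240800 per non-responding neuron (SD, n = 12 neurons). Responding neurons had fewer genes detected, 13424 ± 2548 against 14855 ± 2173. No animal or culture is named, so the differences below describe these neurons and carry no test. Values are log2(scaled count + 1), errors are SD over neurons, and n is 45 responding and 12 non-responding neurons unless stated.

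The first comparison asked which transcripts set ultrasound-responding neurons apart from non-responding ones. Among the fixed lists, markers of MRGPRD nonpeptidergic neurons were higher in responding neurons for 9 of 9 measured members, and markers of myelinated neurons were lower for 13 of 14. The highest difference was in Tmem45b (ENSMUSG00000041737, chromosome 9, 31426196 to 31464462 in GRCm38), at 8.06 ± 5.22 against 2.13 ± 3.50, a difference of 5.93. Acpp, which encodes prostatic acid phosphatase, a marker of nonpeptidergic nociceptors, averaged 7.22 ± 3.77 against 1.58 ± 3.08. It reached a scaled count of 10 in 36 of 45 responding and 2 of 12 non-responding neurons. Fxyd2, a regulatory subunit of the sodium pump, averaged 13.21 ± 2.43 against 8.56 ± 2.50 and was present in every neuron of both classes. Ctxn3, Mal2, Lhfpl2, Synpr, Syt9, Myt1, Gna14, Slpi and Lgals9 complete the 12 highest differences, from 5.01 for Ctxn3 down to 3.45 for Lgals9. Synpr encodes a synaptic vesicle protein, Syt9 a calcium sensor of vesicle release, Gna14 a G protein alpha subunit and Lgals9 a galectin.

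The lowest difference was in Cryab (ENSMUSG00000032060, chromosome 9, 50751325 to 50756636), which encodes a small heat shock protein. It averaged 3.98 ± 4.20 in responding and 9.04 ± 2.01 in non-responding neurons, a difference of -5.06, and was present in 12 of 12 non-responding neurons. Faim2, an inhibitor of Fas-mediated apoptosis, differed by -4.83, the sodium pump regulator Fxyd7 by -4.77 and the synaptic vesicle protein gene Sv2b by -4.60. Cpne6, Ache (acetylcholinesterase), Tmem229b, Ankrd29, Mgst1, Cela1, Fxyd5 and Pcp4l1 followed, from -4.46 to -3.99. Of the 24 genes, 17 went in 1 direction in all 4 sets that hold both classes, which is partly built in because the genes were picked for their difference over the same neurons. Over all genes the share was 15.5%, where chance gives 12.5%, and the set of females of 15 weeks has 1 non-responding neuron. Tmem45b, Lhfpl2, Synpr, Cela1, Fxyd5 and Pcp4l1 each had 1 set going the other way, and Tmem229b was 0 in both classes of 1 set.

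**Figure D1:**
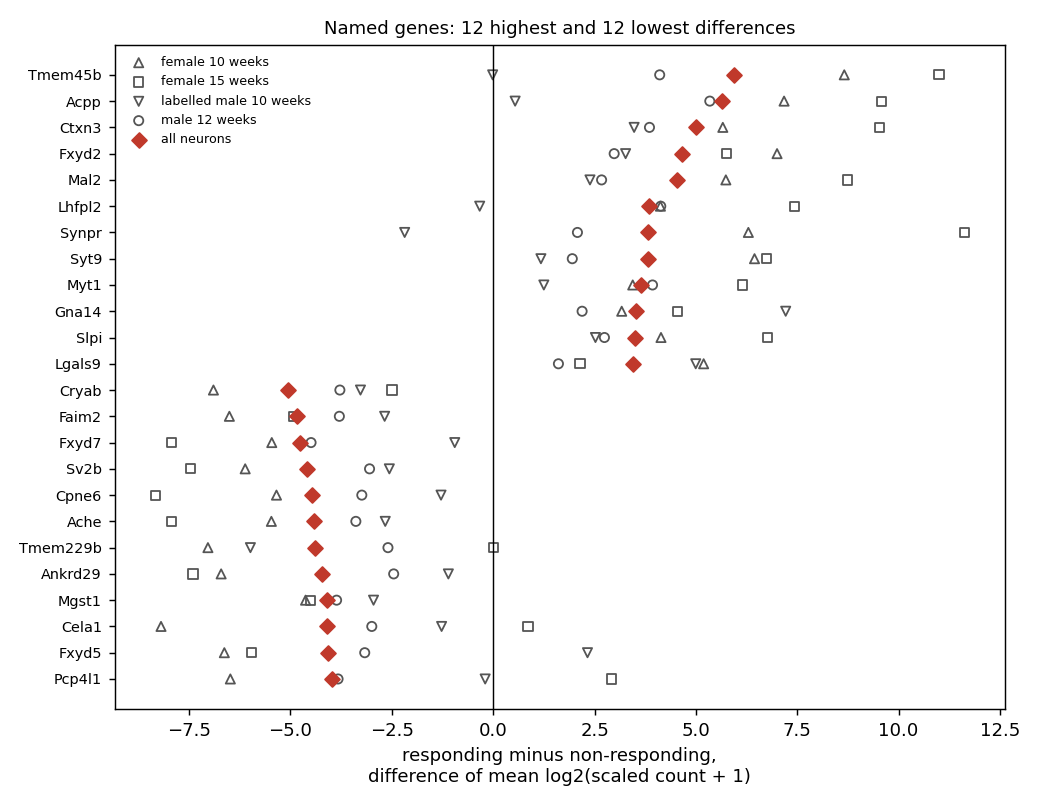
Difference of mean log2(scaled count + 1) between responding and non-responding neurons (x axis) for the 24 named genes (y axis), over all neurons (filled diamonds) and within each of the 4 sex-and-age sets (open symbols). Fxyd2 lies between 2.99 and 7.00 in the 4 sets, while Synpr ranges from -2.18 to 11.62.

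Phf24 encodes GINIP, a regulator of inhibitory G protein signalling that the study's title puts at the centre of the ultrasound response. It lies on chromosome 4 from 42916660 to 42944752 (ENSMUSG00000036062, GRCm38). Phf24 was detected in nearly all neurons of both classes, at a scaled count of 10 or more in 44 of 45 responding neurons (97.8%, interval 88.2% to 99.9%) and 12 of 12 non-responding neurons (100%, interval 73.5% to 100%). Its level was higher in responding neurons, 9.33 ± 2.18 against 7.92 ± 1.70, a difference of 1.40 that is smaller than the SD over either class. The median scaled count was 812.6 against 316.4. Within sets Phf24 was higher in responding neurons by 1.77 in females of 10 weeks, 1.06 in females of 15 weeks and 2.30 in males of 12 weeks, and the difference was -1.72 in the neurons labelled male at 10 weeks. Much of this last value came from 1 responding neuron at 0, and it was -0.48 without that neuron. The value in females of 15 weeks, with 1 non-responding neuron, was 0.67 without 1 of the responding neurons. The mean of these 4 differences was 0.85, and without the males of 12 weeks the pooled difference was 0.69. Pooled differences, for Phf24 and all other genes, include 7 responding neurons from sets with no non-responding neuron. These are the males of 13 weeks and the female of 12 weeks, and both sets averaged above 9.33 for Phf24. Within library pools holding both classes the difference was -0.76, 1.65, 2.44, 1.93 and 1.87. The first of these was 0.15 without the same neuron and -1.97 without 1 of its non-responding neurons. The third, with 2 non-responding neurons, was -0.04 without 1 of them and 4.91 without the other. The fourth rests on 1 non-responding neuron, and the fifth was 1.22 without 1 neuron. A sixth pool code covered 1 neuron only.

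**Figure D2:**
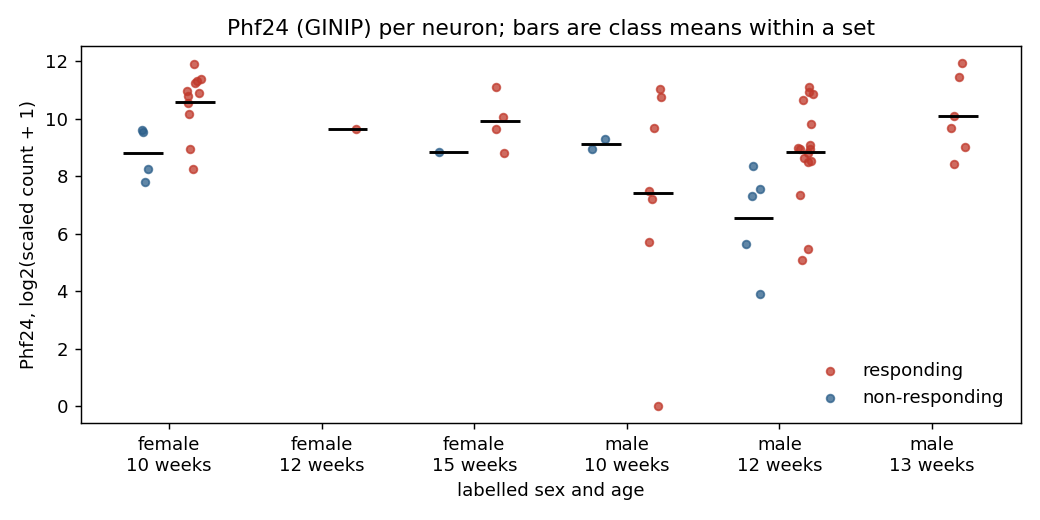
Phf24 as log2(scaled count + 1) (y axis) in each neuron, by labelled sex and age (x axis) and response class (colour); bars are means of the class within a set. Responding neurons averaged higher in 3 of the 4 sets with both classes, and a single responding neuron was at 0.

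Among the lists of subtype markers, the MRGPRD nonpeptidergic list stood highest. MRGPRD marks skin-innervating nociceptors. All 9 measured members averaged higher in responding neurons, with a median difference of 2.02, above all 10000 random lists (percentile 100). The random lists take no account of genes that move together. The estimated correlation over sets was 0.418 within this list, 0.702 within the C-LTMR list and 0.180 within the myelinated list. These estimates rest on only 4 set differences, 1 of them with 1 non-responding neuron. At estimated correlations the added limma camera test called none of the 3 (adjusted p = 0.91 for each). Its unadjusted p was 0.060, 0.52 and 0.19 in the same order. Gna14 averaged 4.65 ± 4.54 against 1.13 ± 1.93, Gfra2, a receptor for neurturin, 3.74 ± 3.31 against 1.05 ± 1.24, and the cation channel gene Trpc3 3.60 ± 3.58 against 1.00 ± 2.13. Mrgprd itself reached a scaled count of 10 in 10 of 45 responding neurons (22.2%, interval 11.2% to 37.1%) and 0 of 12 non-responding neurons (interval 0% to 26.5%). The mean over the list was higher in responding neurons in 4 of 4 sets, by 0.78 to 4.55, and in 5 of 5 pools, by 1.53 to 3.81. The value of 4.55, from females of 15 weeks, and 1 of the pools rest on 1 non-responding neuron each. The remaining 3 sets gave 0.78 to 2.60. Of the MRGPRB4/MRGPRA3 list, only Mrgprb5 and Mrgpra2b passed the low-value filter, and both were higher, by 1.26 and 1.01. Mrgpra3 and Mrgprx1, below the filter, were present in 2 and 3 of 45 responding neurons and in 0 of 12 non-responding neurons. Reads of this receptor family may be shared between near-identical copies.

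C-LTMR markers, genes of the unmyelinated touch neurons that express Th, were higher for 8 of 10 members, with a median of 0.69 at percentile 99.9. The median was 0.24 in neurons labelled male only and 2.26 in neurons labelled female only. Those labelled male include the set of 10 weeks, whose sex label is in doubt, as described below. Fam19a4 averaged 4.77 ± 4.19 against 2.97 ± 4.03, and P2ry1 was higher by 1.84. Th was not higher, at 4.19 ± 4.86 against 4.52 ± 5.15, and was present in 35.6% of responding (interval 21.9% to 51.2%) and 41.7% of non-responding neurons (interval 15.2% to 72.3%). Gfra2 belongs to this list and to the MRGPRD list. The C-LTMR list mean differed by -2.43 in the neurons labelled male at 10 weeks. It was positive in the other 3 sets, with 0.40 in males of 12 weeks.

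The myelinated touch and proprioceptor list was lower for 13 of 14 members, with a median of -1.58 below all random lists (percentile 0). The median was -0.70 without the females of 10 weeks (percentile 1.1) and -0.86 in neurons labelled male only (percentile 0.5). The heavy neurofilament gene Nefh averaged 7.66 ± 2.87 against 9.98 ± 2.80, the sodium channel gene Scn1a 2.63 ± 3.04 against 5.11 ± 3.88, and the BDNF receptor gene Ntrk2 1.75 ± 3.02 against 4.03 ± 3.05. The list mean was lower in responding neurons in 3 of 4 sets and in 4 of 5 pools. It differed by -2.78 in females of 10 weeks, -2.10 in the neurons labelled male at 10 weeks and only -0.26 in males of 12 weeks. It was higher by 0.33 in females of 15 weeks, where 1 neuron was non-responding. In a pool with 2 non-responding neurons it was higher by 1.19. Peptidergic markers went both ways, 4 members higher and 5 lower, with a median of -0.29 at percentile 19.9 that turned positive under 8 of 15 alternatives, up to 1.38 with a stricter low-value filter. Tac1, the substance P precursor, differed by 2.68 and Calcb by 2.07, while Smr2 differed by -2.04. Within sets, Tac1 differed by 6.76 in females of 10 weeks and 9.95 in females of 15 weeks. It differed by 0.02 in males of 12 weeks and by -4.21 in the neurons labelled male at 10 weeks. Calca was present in 97.8% of responding and 91.7% of non-responding neurons. Itch-neuron markers of the SST/NPPB list had 4 of 7 members higher (median 0.33, percentile 94.95), with Nts at 1.79 and Htr1f at -0.88, and Sst itself was present in 2 of 45 and 0 of 12 neurons. Of the TRPM8 cold list only Foxp2 and Cdh8 passed the low-value filter, at -0.05 and 0.03. Below it, Trpm8 was present in 2 of 45 responding and 0 of 12 non-responding neurons, and Rxfp1 in 0 of 45 and 1 of 12.

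**Figure D3:**
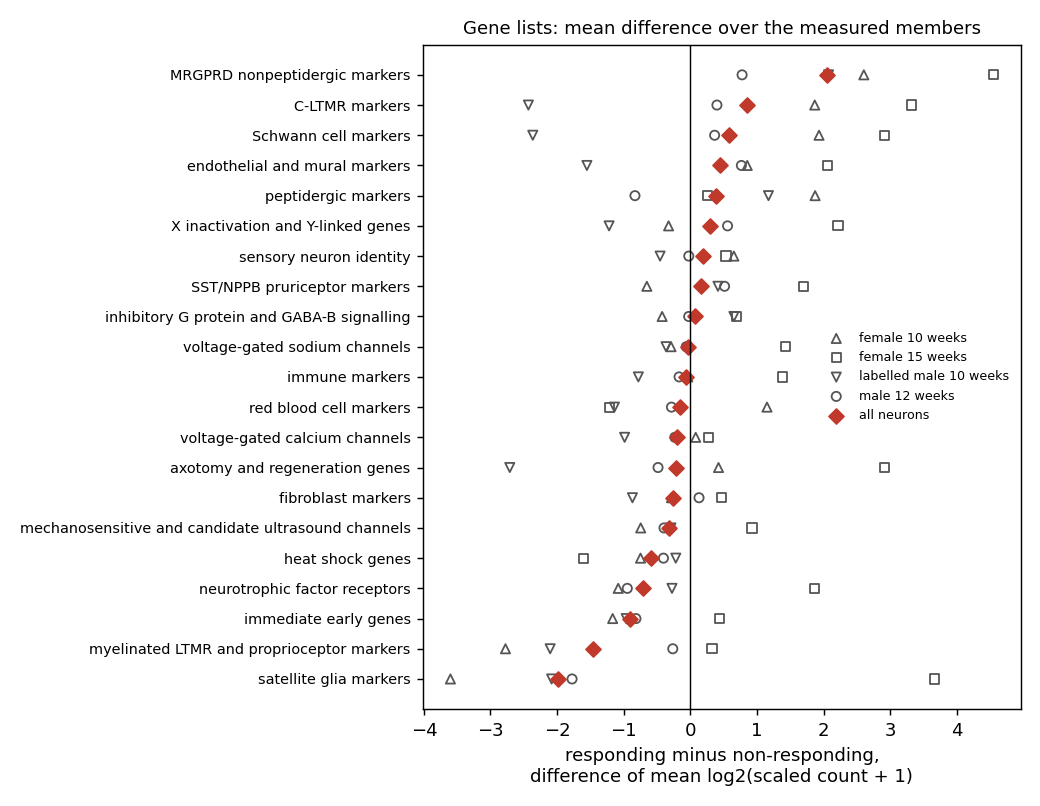
Mean difference over the measured members of each fixed list (y axis) between responding and non-responding neurons, in log2(scaled count + 1) (x axis), over all neurons (filled diamonds) and within the 4 sets (open symbols). The MRGPRD list is above 0 in all 4 sets, whereas the satellite glia list is below 0 in 3 sets and at 3.67 in females of 15 weeks.

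Channels proposed as mechanical or ultrasound sensors did not move together. Of 29 measured, 12 were higher and 17 lower in responding neurons, with a median of -0.58 at percentile 0.93. The median shrank to -0.09 without the 6 neurons with satellite glia transcripts and to -0.10 with a pseudocount of 10. The mean over the list was -0.32 and turned to 0.07 after regression on genes detected. That regression raised the difference of each of the 23 fixed lists it covered, which leave out Phf24. Trpa1, an irritant-gated cation channel gene on chromosome 1 from 14872648 to 14918862, had the highest difference, 3.39. It reached a scaled count of 10 in 19 of 45 responding neurons (42.2%, interval 27.7% to 57.9%) and 0 of 12 non-responding neurons (interval 0% to 26.5%). Trpc3 differed by 2.60, Trpm2 by -2.35, Asic3 by -2.16 and Kcnk10 by -1.89. Piezo2, the principal touch channel, was at 7.74 ± 2.76 against 7.32 ± 2.67, and Piezo1 at 1.84 ± 2.11 against 1.62 ± 1.61. Sodium channel genes split, 5 higher and 6 lower (median -0.24, percentile 46.9). The nociceptor channels Scn10a and Scn11a were higher by 2.90 and 2.22, and Scn1a and Scn4b differed by -2.48 and -2.23. Within sets, Scn10a differed by only 0.02 in males of 12 weeks, and by 4.25 to 7.49 in the other sets. Scn11a differed by -0.04 in females of 15 weeks and by 0.81 to 3.91 in the other sets. Calcium channel genes were 7 higher and 7 lower, with a median of -0.01 (percentile 70.0), Cacnb1 at -1.20 and Cacnb2 at -0.90. Genes of inhibitory G protein and GABA-B signalling were 5 higher and 6 lower (median -0.28, percentile 29.4). This median turned positive under 6 of 15 alternatives, up to 0.75 as a mean of the differences within sets. Among its members were Gnai2 at -1.08, Kcnj6 at 1.00, Oprm1 at 0.96, Kctd16 at 0.96 and Gnao1 at 0.67.

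Of 8 neurotrophic factor receptors, 6 were lower (median -1.23, percentile 0.48), among them Gfra1 by -2.67 and Ngfr by -1.76, while Gfra2 was higher by 2.70. Within sets the mean over these receptors differed by -0.11 ± 1.36 (SD, n = 4 sets), with 1.86 in females of 15 weeks, and the median was -0.70 without the neurons with glia transcripts. Over all neurons the mean over these receptors differed by -0.71, and by -0.22 after regression on genes detected. Ntrk2, at -2.29, and Ntrk3, at -2.04, also belong to the myelinated list, and Ntrk1 and Gfra3 to the peptidergic list. The low percentile of the receptor list therefore partly repeats the myelinated list. Immediate early genes, which are transcribed rapidly after activity or stress, were lower for 14 of 17 members (median -0.46, percentile 6.77). The median was -0.19 as a mean of the differences within sets and -0.80 in neurons labelled male only. Fos averaged 3.17 ± 3.62 in responding and 7.06 ± 2.93 in non-responding neurons, Egr1 2.66 ± 2.91 against 5.95 ± 2.12, and Arc 1.14 ± 2.57 against 3.84 ± 3.64. Egr1 was lower in 4 of 4 sets. The Fos difference was -6.98 in females of 10 weeks and -3.69 in males of 12 weeks, but -0.08 in neurons labelled male at 10 weeks and 2.79 in females of 15 weeks, and the Arc difference was 0.16 and 0 in these last sets. Heat shock genes were lower for 5 of 7 members (median -0.79, percentile 1.48), with Dnajb1 at -2.06 and Hspa1a at -0.96. The median was -0.13 without the males of 12 weeks, -0.24 in neurons labelled male only and -0.34 without the neurons with glia transcripts. The mean over the heat shock list was below 0 in 4 of 4 sets, from -0.22 to -1.60. Over all neurons it was -0.60, and -0.29 after regression on genes detected. Axotomy and regeneration genes were 5 higher and 6 lower (median -0.26, percentile 23.1), with Gap43 at -2.16, Gal at -2.01 and Sox11 at 1.46. This median turned positive under 6 of 15 alternatives, up to 0.97 without the neurons labelled male at 10 weeks. Genes of sensory neuron identity were 5 higher and 5 lower (median 0.07, percentile 45.7). Syt1 differed by 2.25, Rbfox3 by -0.86 and Snap25 by -0.80, and the neuronal gene Uchl1 was at 13.19 ± 0.76 against 13.05 ± 0.44.

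Satellite glia markers, from the cells that wrap sensory neuron bodies, were lower in responding neurons for 5 of 6 members (median -1.97, percentile 0). The median was -0.40 without the 6 neurons described next and -0.72 as a mean of the differences within sets. The first of these values is partly built in, as those neurons were picked by Plp1, Sox10 and Cdh19, members of this list. The genes of the list move together, with an estimated correlation of 0.917 over sets, so they count as far fewer than 6 separate observations. Apoe averaged 1.78 ± 2.40 against 5.12 ± 4.37 and Sparc 1.07 ± 2.58 against 4.23 ± 3.87. Fabp7, the member that was not lower, averaged 2.43 ± 2.46 against 2.28 ± 2.09. It reached a scaled count of 10 in 18 of 45 responding and 3 of 12 non-responding neurons. At least 2 of Plp1, Sox10 and Cdh19 reached a scaled count of 10 in 6 neurons, 4 of them non-responding. Of the Schwann cell list 3 genes were measured (median 0.19, percentile 73.6), with Pmp22 at 1.63 and Mbp at 0.19. Fibroblast genes had a median of 0.33 (percentile 85.6), with Dcn at -2.97 and Pdgfra at 1.86. Endothelial and mural genes had a median of 0.08 (percentile 73.1), with Rgs5 at 1.96 and Cdh5 at 0.36, and immune genes a median of 0.17 (percentile 83.6), with C1qb at -1.12 and Csf1r at 0.51. Red blood cell genes had a median of -0.24 (percentile 39.6), with Hbb-bs at -0.53 and Hbb-bt at 0.42, a pair whose reads may not be separable. The X inactivation and Y-linked list had 4 of 6 members higher (median 0.60, percentile 99.1). Its median was 0.23 without the males of 13 weeks, all responding, and 0.29 as a mean of the differences within sets. The medians of the SST/NPPB, sodium channel, calcium channel, identity, Schwann cell, fibroblast, endothelial, immune and red blood cell lists also took the opposite sign under at least 1 alternative. The mean and the median differed in sign for 4 lists. The mean was 0.39 for peptidergic markers, 0.07 for inhibitory G protein signalling, -0.26 for fibroblast genes and -0.07 for immune genes.

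The second comparison set neurons labelled male against neurons labelled female. The highest difference was in the Y-linked genes Eif2s3y, at 6.05 ± 3.57 against 0.15 ± 0.38, and Ddx3y, at 5.86 ± 3.57 against 0.31 ± 0.58 (SD, n = 36 and 21 neurons). Uty differed by 2.84 and Kdm5d by 1.56. Xist, the transcript of the inactive X chromosome, averaged 1.95 ± 3.43 in neurons labelled male and 5.13 ± 4.33 in those labelled female, and its antisense partner Tsix 1.79 ± 3.27 and 4.86 ± 4.19. No strand setting is stated, so reads of this pair cannot be told apart. The sex label did not match these genes in 1 set. All 27 neurons labelled male at 12 or 13 weeks held Ddx3y or Eif2s3y at a scaled count of 10 or more and 0 held Xist. Of the 9 neurons labelled male at 10 weeks, 0 held either Y-linked gene and 8 held Xist, as did 13 of the 21 neurons labelled female.

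Apart from the Y-linked genes, the highest difference towards the neurons labelled male, over all neurons, was in Pcsk1, a prohormone-processing enzyme, at 7.66 ± 3.41 against 3.77 ± 3.82. Vps45, Samd9l, Haus3, Gsn, Angptl2, Cadm2, Fam111a and Med22 followed, at 2.98 to 2.61. The neurons labelled female were highest, after Xist and Tsix, in Hmox1, the haem-degrading enzyme, at 8.33 ± 2.35 against 5.34 ± 4.11. Nab1, Mir6236, Abr, Myo1a, Rn7s1, Kcnip2, Zfp521, Flnc and Wnt5a had differences of -2.70 to -2.11. Over means of the 6 sets, Pcsk1 was at 2.19, below Vps45 at 4.32, and Kcnip2 turned to 0.35. That order and that sign rest on the set of females of 12 weeks, which is 1 neuron. Without it Vps45 was at 3.23, again below Pcsk1, and Kcnip2 at -1.60. Over the 6 set means Mir6236 was at -1.34, Rn7s1 at -0.58 and Wnt5a at -0.56. Without the female of 12 weeks these 3 genes were at -1.285, -1.65 and -1.88. Mir6236 averaged 6.93 in females of 10 weeks but 2.41 in females of 15 weeks, below each set labelled male (2.90 to 4.18). Phf24 differed by -1.51, at 8.48 ± 2.39 in neurons labelled male and 9.99 ± 1.18 in those labelled female. Males of 13 weeks averaged 10.10, within the female sets (9.65 to 10.11), and the neurons labelled male at 10 weeks, whose label is in doubt, averaged 7.79. Without the males of 12 weeks only 4 of these 24 genes were named again, and without the neurons labelled male at 10 weeks 15 were. The labelled sexes were spread unevenly over the library pools, and no difference between them was taken within pools. Differences between pools may therefore enter all of these values.

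**Figure D4:**
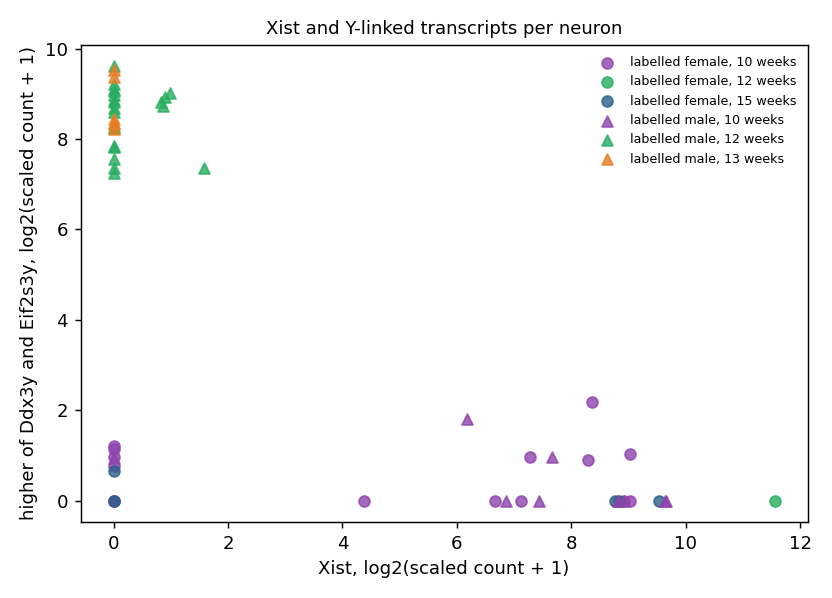
Xist (x axis) against the higher of Ddx3y and Eif2s3y (y axis) in each neuron, both as log2(scaled count + 1), with symbol for labelled sex and colour for age. The neurons labelled male at 10 weeks lie with the neurons labelled female, and 8 of these 9 neurons hold Xist.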

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

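Of 46 results, namely the 24 named genes, Phf24 and 21 lists, 1 had a set far from the other 3. The mean difference of the voltage-gated sodium channel list was 1.43 in females of 15 weeks, where 1 neuron was non-responding, and between -0.365 and -0.0622 in the other sets. Chance alone marks about 1 group in 20 in this way. By the added limma fit over sets, no gene had a response difference that differed between the labelled sexes at an adjusted p under 0.05. At an unadjusted p under 0.05, 671 did, fewer than the 1090 that chance gives. These counts cannot decide whether the response difference depends on sex. The fit rests on few sets, and the sex label of 1 set labelled male is in doubt. The females of 15 weeks, with 1 non-responding neuron, are also among its sets.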

How the results depend on the processing

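The sets, the neurons with glia transcripts and the limma fits were chosen after seeing the data. The Phf24 difference of 1.40 stayed positive under all alternatives run, from 0.69 without the males of 12 weeks to 2.00 without the neurons labelled male at 10 weeks, and from 1.04 to 1.62 when 1 neuron was left out in turn. Of the 360 values of the 24 named genes under other settings, none changed sign. That is largely built in, as the genes were picked for large differences over the same neurons. Of the 24 genes, 8 were named again in neurons labelled male only and 14 in those labelled female only. Without the females of 10 weeks 15 were, and without the males of 12 weeks 15 were. Fewer neurons were compared in each of these settings. For the labelled sexes, 13 of 24 were named again with the TPM table (the cause was not tested), and 8 without the females of 10 weeks, 15 without the neurons labelled male at 10 weeks and 4 without the males of 12 weeks. Of 21 lists, 8 had a median outside the central 95% of random lists, and 6 to 9 did under the alternatives; the MRGPRD list stayed at percentile 100 in all 15, and 12 lists took the opposite sign of median in at least 1. The median difference over all genes was -0.10, and it was -0.27 with a pseudocount of 0.1 and 0.00076 with a pseudocount of 10. Th was present in 66.7% of responding neurons at a scaled count of 1. Calca was present in 100% of responding and 100% of non-responding neurons at 1, and in 86.7% of responding neurons at 50, by the threshold alone.

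In the added fits, limma called 0 genes between response classes at an adjusted p under 0.05 over the 4 sets, with 1332 at an unadjusted p under 0.05, 0 of 193 genes adjusted over the list alone, and 0 with no replicate block (1635 unadjusted) or in the other 9 settings. Camera with a preset correlation of 0.01 called the MRGPRD list (adjusted p = 7.5e-08) and the myelinated list (adjusted p = 0.042). With an estimated correlation neither was called (adjusted p = 0.91 for both), and the preset call of the myelinated list was also lost with no replicate block (adjusted p = 0.063), with a pseudocount of 0.1 (adjusted p = 0.18), and without the females of 10 weeks (adjusted p = 0.54) or the neurons labelled male at 10 weeks (adjusted p = 0.18). The preset test also called the satellite glia list with weights and without the females of 15 weeks, and the C-LTMR list without the neurons labelled male at 10 weeks. At an estimated correlation no list was called in any of these settings. Flipping the classes within sets gives only 8 splits, too few for a share under 0.05: 1 split, the real one, reached 1332 genes (highest other 1017), and 6 reached the real 2 lists (highest other 4). For sex, limma over 6 sets called 0 genes, with 631 unadjusted, and without the neurons labelled male at 10 weeks 0, with 359 unadjusted. Of the 10 splits of the 6 sets, also too few, 6 gave as many as 631 and the highest other gave 1704. Pairing was by set only, as the replicate numbers follow deposit order. The count test was not run, as no culture is named. Leaving out neurons with few detected genes removed 0 neurons and tested nothing, and no classes could be merged. A marker at 0 of 12 neurons allows a share of up to 26.5%.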

Other observations

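The tests on the sex labels, on library pools, on the slope with genes detected and on Apoe and Sparc were chosen after the results were seen. Leaving out the neurons with glia transcripts was chosen after seeing the data.

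The sex labels of 1 set went against its transcripts. A wrong sex label for the set is a candidate explanation: 8 of the 9 neurons labelled male at 10 weeks held Xist, and 0 held Ddx3y or Eif2s3y, the most abundant Y-linked genes here. The choice of these 2 genes was made after it was seen that 1 of the 9 neurons held Uty, at 4.28 on the log2 scale. RNA of female cells added to male neurons would leave the Y-linked transcripts in place, and 0 of the 9 held either gene, against 27 of 27 other neurons labelled male. Too few reads is also argued against, as the median depth of the set was 0.925 of that of the others. No sample was relabelled, no biological explanation was tested, and if the label is wrong this set need not come from other animals than the females of 10 weeks.

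The higher level of the MRGPRD list in responding neurons, 2.04 for the list mean, was set against technical differences between the classes. Genes detected are argued against by the slope: responding neurons had fewer, so the list would have to change by -1.43 per 1000 genes, and it changed by 0.163 (SE 0.131). Regression on genes detected raised the difference of 23 of 23 fixed lists it covered, which leave out Phf24, so its value of 2.28 here decides nothing. Without the 6 neurons with satellite glia transcripts the difference was 2.08, positive in 4 of 4 sets. It was positive in 5 of 5 library pools, 1 of which has 1 non-responding neuron, and in 4 of 4 of the others. These values argue against genes detected, glial RNA and library pool as the whole cause. A larger share of MRGPRD-type nociceptors among responding neurons was not tested apart from this list and stays open. At a scaled count of 10 the intervals for Gfra2, also a C-LTMR marker, do not overlap (26 of 45 neurons, 42.2% to 72.3%, against 0 of 12, 0% to 26.5%). At a scaled count of 1 the Gfra2 shares were 0.60 and 0.417. The intervals for Mrgprd itself overlap (11.2% to 37.1% and 0% to 26.5%), as do those of every other MRGPRD marker. All these intervals cover counting error only and are no test across neurons. Unnamed cultures, and which neurons were picked for collection, also stay open.

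Glial transcripts may come from satellite glia collected with the neuron by the pipette. Of the 6 neurons with at least 2 of Plp1, Sox10 and Cdh19, 100% also held Apoe and Sparc, against 3 of the 51 others, and their median Apoe and Sparc were 6.66 and 8.50 against 0 and 0. Fabp7, from the same list, was at 4.31 against 1.39. Deeper libraries are argued against, as the median reads of the 6 neurons were 0.995 of those of the others. The 4 non-responding neurons among the 6 came from females of 10 weeks and males of 12 weeks, and the 2 responding ones from females of 15 weeks, so whether glial RNA goes with the lack of a response stays open.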
